A study of Mus musculus with 6 samples.

How the data were processed

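RNA was sequenced from common myeloid progenitors, a bone marrow population that gives rise to granulocytes, monocytes, erythroid cells and platelets. The cells were sorted from mice that had been transplanted with bone marrow carrying a doxycycline-inducible U2AF1 transgene, either wild type or with the S34F substitution, together with the rtTA transactivator. Per the labels' protocols, the mice were given doxycycline for 5 days, more than 6 weeks after transplantation. Each of the 6 libraries, 3 per genotype, was made from pooled marrow of 4 to 5 mice, so the replicates were separate pools of transplanted animals. Marrow donors shared between pools were not excluded. The genotype was taken from the sample titles. The genotype entry in the sample characteristics read S34F for all 6 samples and was not used, because the titles and the column names of the tables both separated S34F from WT.

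Per the labels' protocols, ribosomal RNA was depleted, strand-specific libraries were made and paired reads of 100 bp were sequenced. The series text names TopHat 2.0.8 and the mm9 build. Per the submitters' processing notes, Bowtie2 2.1.0, TopHat2 2.0.8, Cufflinks 2.1.1, HTSeq 0.5.4p1 and DESeq2 1.6.1 were also part of the processing, with no role given for any of them. Whether the counting used the strand of the reads, and the annotation it used, are not given in the sources used here.

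The authors deposited raw read counts for 13932 genes and for 151811 splice junctions, in a column per library, with no normalization. The gene table also holds, per the file headers, the authors' fold change as a ratio, its log2 value and raw and adjusted p-values. The junction table holds, per the file headers, a DEXSeq test of each junction within its gene, with a log2 fold change, p-values, a dispersion and test statistic (a score with no fixed range) and a mean count used as a coverage signal. It also repeats the gene counts and gives FPKM per gene by the authors, which entered no test here. The authors' fold changes and p-values were used only where the text names their table. The smallest total of any deposited junction over the 6 libraries was 12 reads and the smallest total of any gene was 54.

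The reference genome used here was the mouse NCBI build that corresponds to mm9. Of the gene identifiers, 13900 (99.77%) were found in its annotation. At the junction positions as printed, 0% of the GT-AG introns carried these bases. After a shift of 1 base inward at each end, 99.985% did, so the printed positions are the last and first exon bases and all coordinates below use the build mm9, counted from 1.

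Gene counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the package's default expression filter and the quasi-likelihood F test, which left 13905 genes. Levels are given as counts scaled by library size and TMM factor (CPM). DESeq2 1.42.0 with its default Wald test was the alternative tool. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold unless another is stated. All tests were two-sided, except the tests of lists among genes with altered splicing, which asked for more genes than expected among genes matched on junction reads by random draws, and again by Fisher's exact test without matching. A total of 31 gene lists, for RNA processing, translation, stress, cell cycle, metabolism and blood cell types that the sort could hold, was tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

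Splicing was tested on junction counts in 4 ways. For introns that share a donor, the reads of each acceptor were set against those of the other acceptors, and likewise for donors that share an acceptor. For cassette exons of 10 to 1000 nt, the summed reads of the upstream and downstream inclusion junctions were tested against the reads of the skipping junction, with the pair of flanking exons that had most reads. The inclusion level in percent used the average of both inclusion junctions. Candidate exons whose interval itself held a junction were left out. For alternative 3' splice sites 3 to 500 nt apart, the share of the proximal site was used. An event needed 20 reads in every library, and both of its forms had to reach 2% of the reads (1% for the tests of acceptors and donors). Each event entered edgeR as 2 counts per library, with a term for each library, a term for the form and a term for the interaction of genotype and form, which was tested. DESeq2 used the same model, and limma used log2 ratios with 0.5 added to each count. Overlapping cassette exons, and the forms of a single site, share reads and are not independent. The base at intron position -3, just before the acceptor AG, was read from the genome.

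On simulated data with 200 changed features per test, 50 genes at each fold size, edgeR recovered 10% of the genes changed 1.5-fold, 54% of those changed 2-fold, 88% at 4-fold and 96% at 8-fold, with 15 false calls among 13905 genes. DESeq2 recovered 30%, 78%, 92% and 96% of the same genes with 53 false calls. In both tools the false calls were a larger share of the called genes than the threshold of 0.05 allows, more so in DESeq2. For the splicing tests, the simulated spread between libraries was set to an SD of 0.15 in natural log odds for every event. It was not taken from these libraries, so the values below need not hold for them. In the real data the tools stood in the other order, with 0 cassette exons called by edgeR and 103 by DESeq2. For cassette exons, with 100 changed at each size, edgeR recovered 44% at a log2 odds change of 1 and 91% at 2 with 5 false calls among 8594 exons. DESeq2 recovered 6% and 66% with 0 false calls. For alternative 3' splice sites edgeR recovered 38% and 89% with 8 false calls among 3577 pairs, also above the threshold as a share of its calls, and DESeq2 12% and 69% with 0. For acceptor use the recovery was 16% and 82% with edgeR and 0% and 36% with DESeq2 over 29709 tests. For donor use it was 21% and 75% with edgeR and 2% and 41% with DESeq2 over 30084.

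The groups, tests, gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. That rule named U2af1, up to 12 genes with the highest and 12 with the lowest fold changes at a mean of 5 CPM or more among genes past the threshold, or the 10 genes of lowest p if fewer than 5 passed, with up to 4 members per list. For splicing it named the 8 largest gains and losses of cassette inclusion and the 5 largest of proximal site share, among called events whose libraries did not overlap between genotypes. Because edgeR called 0 genes, the 10 genes of lowest edgeR p were named. Because edgeR called almost no splicing events or list members, the rule for these was applied to the DESeq2 calls, a choice made after the edgeR counts were known.

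Same-numbered libraries deviated together. Over 12143 genes, the correlations of their deviations from the group means were 0.379, 0.370 and 0.156 for numbers 1, 2 and 3. Among the WT libraries, each S34F library correlated best with that of its own number. The numbers were therefore treated as pairs in a fit with the replicate number as a block. Without genes on the sex chromosomes the correlations were 0.211, 0.305 and 0.0683. No 2 libraries were alike within sampling noise. Other alternatives were scaling by DESeq2 size factors or library size alone, other filters and read minima, a threshold of 0.10, a minimum change of 10 percentage points, and leaving out each library in turn. Alternatives chosen after seeing the data were DESeq2 with libraries left out or with the block, leaving out both replicate 1 libraries, leaving out junctions with 20 or more reads in each of 3 libraries and 2 or fewer in total in the others, and the sets of splicing events with an unadjusted p under 0.01. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1.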

Results

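The data were gene and splice junction read counts from common myeloid progenitors of mice in which a U2AF1 transgene, wild type (WT) or S34F, was induced for 5 days. U2AF1 is the small subunit of the splicing factor that binds the AG at the 3' end of introns, and the S34F substitution recurs in myelodysplastic syndromes and acute myeloid leukaemia. The comparison asked which genes changed in level and which splicing choices changed after a short induction of the mutant. There were 3 libraries per genotype. The S34F libraries held 51862032, 46827909 and 50337935 gene counts and the WT libraries 54727541, 71237275 and 94562984. Junction counts were 44589528, 41003848 and 42977184 against 46491099, 62477285 and 82730420.

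U2af1 itself was at similar levels in both genotypes. Its counts were 6222, 6311 and 6159 in S34F and 5791, 8871 and 12060 in WT. This was 126 ± 9.13 against 119 ± 12.6 CPM, which are counts scaled to a common library size (mean ± SD, n = 3; exact permutation p = 0.6). The log2 fold change was 0.07 and a standard error of 0.11 (edgeR adjusted p = 0.815; chromosome 17, 31784027 to 31795699). Reads of the transgene and of the endogenous gene were not separated here, so these counts do not check the labels. Ddx3y, a Y-linked gene, had 5714 counts in S34F replicate 1 and 5580 in WT replicate 1 and 0 in every other library. Xist, transcribed from the inactive X, had 1 and 5 counts in those libraries. The sequenced cells of replicate 1 were therefore male in both genotypes, and those of the other replicates female. The mice had received transplanted marrow, so this need not be the sex of the pooled recipient mice.

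Some properties of the libraries differed with genotype. Mitochondrially encoded genes took 2.63 ± 0.174% of the counts in S34F and 1.72 ± 0.399% in WT, and the mitochondrial ribosomal RNA mt-Rnr2 alone 0.571 ± 0.0773% against 0.230 ± 0.206%. The small nuclear RNA 7SK took 2.25 ± 0.239% against 3.01 ± 0.234%, and the 10 most abundant genes 8.22 ± 0.215% against 9.23 ± 0.371%. Total gene counts were lower in every S34F library than in any WT library. For each of these measures the genotypes did not overlap (exact permutation p = 0.1, the smallest that 3 libraries against 3 allow). Junction reads per gene read were 0.863 ± 0.0113 and 0.867 ± 0.0153 (exact p = 0.9). The share of junction reads in unannotated junctions was 0.772 ± 0.0270% and 0.765 ± 0.0143% (exact p = 0.8), and the share in junctions that skip annotated exons was 7.96 ± 0.00668% and 8.03 ± 0.141% (exact p = 0.5).

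At the gene level, the 10 genes of lowest edgeR p included H2-Aa and H2-Ab1, MHC class II genes that encode chains presenting antigen to T cells, with log2 fold changes of -2.71 and -1.74 in S34F progenitors. H2-Eb1, a further MHC class II gene, had -2.38. H2-Aa was at 13.8 ± 5.70 CPM in S34F and 90.3 ± 25.4 CPM in WT, and H2-Ab1 at 24.6 ± 3.16 against 82.0 ± 21.1. Plbd1, a lysosomal phospholipase-like gene, was at 9.99 ± 1.22 against 32.1 ± 4.98 CPM (log2 fold change -1.68) and Ms4a6c, a membrane protein gene of myeloid cells, at 77.6 ± 2.96 against 149.6 ± 10.4 CPM (-0.95). In the other direction Phlda3, a p53-induced inhibitor of Akt, was at 8.04 ± 3.50 against 1.47 ± 0.328 CPM (2.45).

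edgeR called 0 of 13905 genes at an adjusted p under 0.05. It gave 1265 genes an unadjusted p under 0.05, 611 higher and 654 lower, where 695 would be expected by chance, and the lowest adjusted p was 0.0677, for Plbd1 and Ms4a6c. With the replicate number as a block, edgeR called 5 genes, all lower in S34F. These were H2-Aa (adjusted p = 0.00493), H2-Eb1 (0.00651), H2-Ab1 (0.0325), Plbd1 (0.0424) and Ciita, the transactivator of MHC class II genes, which is named because the count was small and after its values were seen (2.58 ± 0.669 against 11.7 ± 4.01 CPM, log2 fold change -2.19, adjusted p = 0.0382). DESeq2 called 96 genes, 34 higher and 62 lower, and 445 with the block. In all 96 the ranges of the genotypes did not overlap. Chance gives this for 10% of unselected genes, and selection by DESeq2 favours it, so it is no further evidence for these genes. The authors' deposited table has 86 genes under an adjusted p of 0.05, 34 higher and 52 lower, and all 86 were among the 96.

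The remaining genes of lowest edgeR p were also lower in S34F and were DESeq2 calls. They were Klrk1, a receptor of natural killer and T cells (log2 fold change -2.05, DESeq2 adjusted p = 3.63e-11), Tlr3, a sensor of double-stranded RNA (-2.60, 1.72e-07), Ifi205, an interferon-inducible gene (-2.75, 3.25e-11), Slc46a3, a lysosomal transporter gene (-1.57, 3.11e-08), and Itga1, an integrin gene (-1.20, 1.18e-07). For Plbd1, Ms4a6c, H2-Ab1, H2-Aa and Phlda3 the DESeq2 adjusted p was 7.05e-17, 1.82e-13, 4.72e-12, 3.56e-13 and 3.34e-09. H2-Ab1 and H2-Aa lie on opposite strands of chromosome 17, at 34400154 to 34406363 and 34406276 to 34424772, and overlap at their 3' ends, and Ms4a6c has close relatives, so shared reads were not excluded for them. The counts rested on single libraries: without WT replicate 1, edgeR called 1172 genes and DESeq2 2502, while DESeq2 called 43 without WT replicate 3 and 55 without S34F replicate 2.

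**Figure D1:**
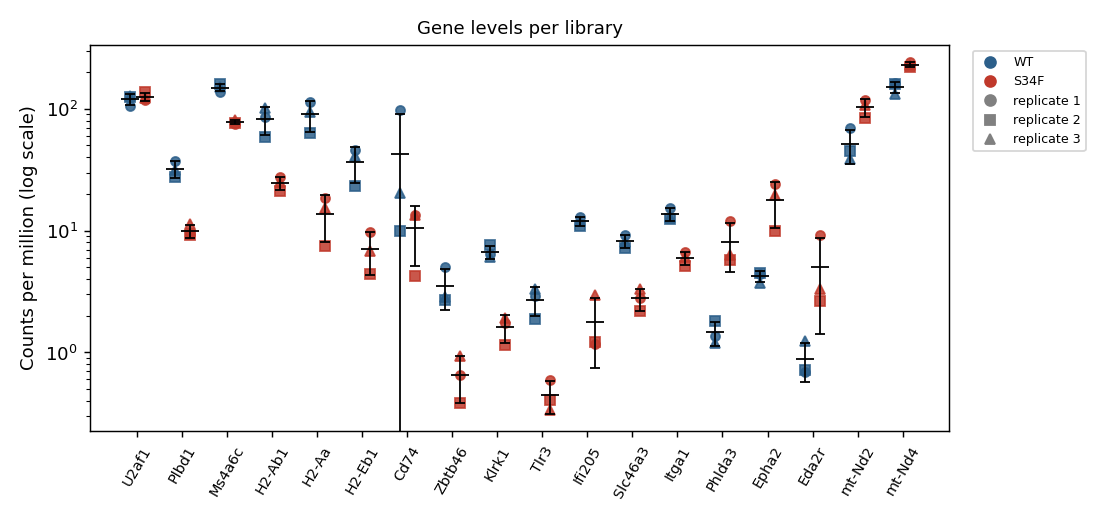
CPM (log axis) of named genes in each library, WT in blue and S34F in red, with the replicate number as the marker shape and bars for the mean ± SD. H2-Aa lies between 63.0 and 113 in WT and between 7.49 and 18.5 in S34F, while Cd74 overlaps between the genotypes, with 97.4 in WT replicate 1 and an SD that reaches below the axis.

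Of the 31 gene lists, 13 passed camera with a preset correlation, and none with an estimated correlation. No list passed fry for a change in a common direction (lowest fry adjusted p = 0.181). For changes in mixed directions, only the dendritic cell and macrophage list passed fry (adjusted p = 0.00891). The mitochondrially encoded genes were higher in S34F, all 14 of the 14 measured, with a median log2 fold change of 0.77 (camera adjusted p = 6.49e-17, adjusted p = 0.303 with an estimated correlation). Of these, 10 passed edgeR adjusted over the list alone, and DESeq2 called 5 over all genes. The complex I genes mt-Nd2 and mt-Nd4 were at 103 ± 16.6 against 51.2 ± 16.2 CPM and 231 ± 10.01 against 150.5 ± 16.8 CPM (log2 fold changes 1.01 and 0.62, DESeq2 adjusted p = 0.00533 and 0.000740), and mt-Nd1 and mt-Nd5 had 0.75 and 0.49. Nuclear copies of mitochondrial genes could not be told apart in the counts. The mitochondrial share moved together with that of mt-Rnr2, a ribosomal RNA, at 0.571% against 0.230% of all counts. The list median was 0.54, 0.64 and 1.17 in replicate pairs 1, 2 and 3. Over WT replicates 1, 2 and 3, mt-Rnr2 fell from 0.454% to 0.189% and 0.0484% as total gene counts rose. In S34F, with totals closer together, it was at 0.657%, 0.549% and 0.507%. Totals also differed between the genotypes, so a genotype effect cannot be told apart here from library depth or ribosomal RNA depletion.

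The dendritic cell and macrophage list was lower in S34F, with 15 of the 23 measured members of 30 listed lower and a median log2 fold change of -0.46 (camera adjusted p = 6.27e-10, adjusted p = 0.303 with an estimated correlation). By edgeR, 6 members passed adjusted over the list alone, all lower and all also DESeq2 calls over all genes. Besides the MHC class II genes these were Zbtb46 (log2 fold change -2.42), Batf3 (-2.37) and Clec9a (-1.97), which are a transcription factor of conventional dendritic cells, a transcription factor of their cross-presenting subset and a surface receptor of that subset. Cd74, the invariant chain of MHC class II, was at 10.5 ± 5.36 against 42.5 ± 47.8 CPM, with overlapping libraries (edgeR adjusted p = 0.548).

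The p53 target list was higher in S34F, with 23 of 30 measured members higher and a median log2 fold change of 0.31 (camera adjusted p = 1.37e-08, adjusted p = 0.688 with an estimated correlation). By edgeR, 6 members passed adjusted over the list alone, all higher. They were Phlda3, the receptor genes Epha2 (17.8 ± 7.21 against 4.23 ± 0.448 CPM, log2 fold change 2.08) and Eda2r (2.51), Zmat3 (1.66), Trp53inp1 (0.74) and the apoptosis gene Bax (0.35). DESeq2 called Phlda3, Epha2 and Eda2r over all genes. The median of the list was 0.56 in the replicate 1 pair, which was male, against 0.12 and 0.17 in the other pairs, and the list did not pass without both replicate 1 libraries (camera adjusted p = 0.133).

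Genes of SR proteins and hnRNPs, which bind pre-mRNA and steer splice site choice, were higher in 39 of 49 members (median 0.20, camera adjusted p = 1.51e-06, adjusted p = 0.688 with an estimated correlation), with Hnrnpa2b1 at 649 ± 90.9 against 382 ± 97.6 CPM (log2 fold change 0.76, DESeq2 adjusted p = 0.0290). The factors that recognise 3' splice sites, a list that holds U2af1, did not pass (camera adjusted p = 0.158), though DESeq2 called 1 member, the helicase gene Ddx46 (log2 fold change 0.50, adjusted p = 0.0372). The erythroid list was lower in 23 of 27 members (median -0.54, camera adjusted p = 0.000259), although in the replicate 2 pair its median was -0.0061. Replication-dependent histone genes were lower in 39 of 50 members (median -0.14, camera adjusted p = 0.000704), with Hist1h4c at 266 ± 58.3 against 467 ± 32.0 CPM (log2 fold change -0.81, DESeq2 adjusted p = 0.00144). In the replicate 3 pair the histone median was 0.09, in the other direction. Histone genes are a family of near-identical copies, and for the erythroid and histone lists the adjusted p was 0.688 with an estimated correlation. The interferon response list was lower (median -0.15, camera adjusted p = 0.0374) and did not pass with an estimated correlation (adjusted p = 0.688) or with the replicate block (0.0607). Its median was 0.17 in the replicate 2 pair, in the other direction, and its DESeq2 call was Trim21 (log2 fold change -0.54).

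Cassette exons, which are either included or skipped, were lost more often than gained in S34F. Jmjd1c, a histone demethylase-related gene, lost the most: an exon of 148 nt on chromosome 10 (66680786 to 66680933, 144 coding bases, not an annotated exon as such) was included at 24.7 ± 10.6% in S34F and 67.0 ± 4.36% in WT, a change of -42.3 percentage points. Kdm6a, an X-linked histone demethylase gene, lost a coding exon of 135 nt by -24.9 points (56.6 ± 6.06% against 81.5 ± 5.20%), and Fmr1, the gene of the fragile X RNA-binding protein, a coding exon of 63 nt by -20.3 points (31.5 ± 6.09% against 51.8 ± 0.590%). In the other direction a 78 nt form of an exon of Rtel1, a DNA helicase gene, rose by 35.8 points (83.3 ± 5.90% against 47.6 ± 9.76%), and an exon of 81 nt in Map3k7, the gene of the kinase TAK1, by 25.3 points (69.4 ± 6.16% against 44.1 ± 2.51%). These were DESeq2 calls, with adjusted p = 0.0188, 0.0285, 0.0432, 0.0370 and 0.00861.

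Of 8594 cassette exons in 4317 genes, edgeR called 0. It gave 874 an unadjusted p under 0.05, 290 gained and 584 lost, where 430 would be expected, and 232 a p under 0.01, 68 gained and 164 lost (exact binomial p of the split 2.49e-10), where 86 would be expected. DESeq2 called 103 exons in 91 genes, 29 gained and 74 lost (exact binomial p = 1.07e-05), of which 42 changed by 10 points or more, and limma called 0. Both binomial tests count exons of the same 6 libraries, and some of these exons share reads. Their p-values therefore do not measure the spread between replicates. In all 103 the genotypes did not overlap, which chance gives for 10% of unselected exons and which selection by DESeq2 favours. The DESeq2 count was 29 with the replicate block, 32, 17 and 62 without S34F replicates 1, 2 and 3, and 33 without WT replicate 3. The median depth was 313 reads per exon and library.

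The other named losses, between -21.0 and -18.9 points, were exons of Aim2, a sensor of cytosolic DNA (90 nt, noncoding, 68.4 ± 2.44% against 89.4 ± 5.18%), Dmtf1, a cyclin D-binding transcription factor gene, D15Ertd621e, Fcgr2b, the inhibitory Fc receptor (141 nt, 44.9 ± 0.638% against 64.0 ± 1.59%), and Cep70, a centrosomal gene. The other named gains were exons of Med24, a Mediator subunit gene (57 nt, 37.2 ± 6.30% against 14.8 ± 2.28%), Anapc16, Camkk2 and Pts, between 16.2 and 22.4 points, a longer form of the Rtel1 exon (117 nt, 21.2 points) and a longer form of the Map3k7 exon (137 nt, 25.1 points). Among the fixed lists, Hnrnpa2b1 lost an exon on chromosome 6 (51414427 to 51414546), at 30.7 ± 0.879% against 49.1 ± 3.35% (DESeq2 adjusted p = 0.000395), as the level of the gene rose by DESeq2. Clk1, a kinase of SR proteins, lost an exon by -5.46 points (DESeq2 adjusted p = 0.00847) and Mbnl1, a splicing regulator, by -9.72 points (0.0113). The translation factor gene Eif4a2 lost an exon by -14.1 points (DESeq2 adjusted p = 0.0137). The exons with the lowest edgeR adjusted p, named after their values were seen, were overlapping forms of a noncoding exon of Morf4l2 (0.0566 and 0.0690, changes of -8.82 and -14.2 points).

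**Figure D2:**
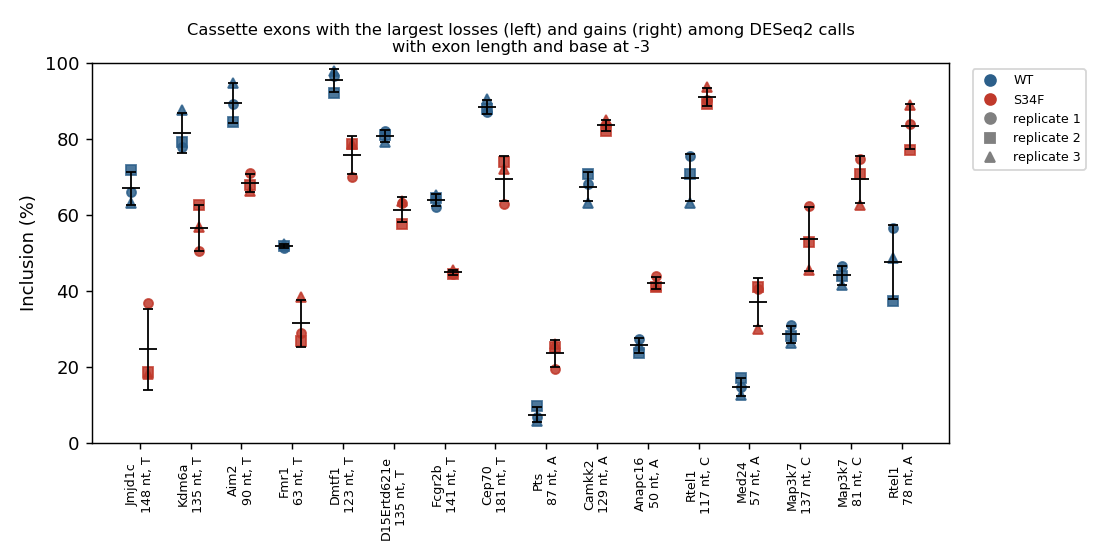
Inclusion (%) of the 16 named cassette exon forms in each library, WT in blue and S34F in red, with the replicate number as the marker shape and bars for the mean ± SD; labels give the gene, exon length and base at intron position -3. All 8 lost exons on the left carry T at that position, and the gained exons on the right carry A or C.

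At alternative 3' splice sites, where a donor is joined to either of a pair of nearby acceptors, shifts fell in both directions. In Top2a, the gene of topoisomerase II alpha, the share of the proximal acceptor was 70.6 ± 2.83% in S34F and 89.1 ± 1.35% in WT (-18.5 points, DESeq2 adjusted p = 8.87e-10; chromosome 11, acceptors at 98854728 and 98854640). In Picalm, a clathrin adaptor gene, the proximal share was 42.4 ± 1.89% against 25.9 ± 1.77% (16.5 points, adjusted p = 0.000318; chromosome 7, acceptors at 97339650 and 97339665). The largest shifts were -35.1 points in Hexdc and 33.1 points in Cep70, at as few as 37 and 57 reads in a library. The other named shifts away from the proximal site were in Ccdc76, Tor1aip2 and Rfng, between -21.4 and -17.0 points, and those toward it in Mtpap, Arrdc1 and the noncoding gene 9030619P08Rik, between 11.5 and 14.3 points. Of 3577 pairs in 2655 genes edgeR called 0, with 241 at an unadjusted p under 0.05 where 179 would be expected, while DESeq2 called 56, 19 toward and 37 away from the proximal site (exact binomial p = 0.0222), and limma 4. Of the 64 pairs with an unadjusted p under 0.01 by edgeR, 25 moved toward and 39 away from the proximal site (exact binomial p = 0.103). Both binomial tests again count events of the same libraries and not replicates. The mitosis genes Ect2 (5.57 points), Bub1 (-4.57) and Hmmr (-4.39) were among the DESeq2 calls.

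Over all introns that share a donor, edgeR called 0 of 29709 acceptor choices, with 2218 at an unadjusted p under 0.05 where 1485 would be expected, while DESeq2 called 368 in 205 genes and limma 45. Over introns that share an acceptor, edgeR called 3 of 30084 donor choices, with 1923 at an unadjusted p under 0.05 where 1504 would be expected, while DESeq2 called 233 in 132 genes and limma 56. Of the 3 calls, 2 were both forms of an intron of the ribosomal protein gene Rpl7a, whose minor GC-AG intron (chromosome 2, 26767676 to 26767885) took 0% of the reads in S34F and 2.19 ± 0.287% in WT (edgeR adjusted p = 0.00544). The other was an intron of Arpc1b, a subunit of the actin-nucleating Arp2/3 complex (chromosome 5, 145884793 to 145885455), with 4.31 ± 0.317% in S34F and 0% in WT (0.0126). Both minor introns were among the junctions with many reads in every library of a genotype and none or almost none in the other. The source of such junctions stays open, and without them the edgeR count of donor choices was lower. With the replicate block 0 donor choices were called (adjusted p = 0.921 for these), and edgeR called 0 without WT replicate 1, 1 without WT replicate 3 and 5 without S34F replicate 2 or WT replicate 2. The authors' deposited junction table has 512 junctions under an adjusted p of 0.05 and 742 under 0.10, in 633 genes.

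The base just before the acceptor AG, at intron position -3, separated lost from gained exons. Of the 164 exons lost at an unadjusted p under 0.01, 144 had T at this position, 14 had C and 5 had A. Of the 68 gained, 2 had T, 50 had C and 16 had A (log2 odds 7.65 for T against C in lost exons, Fisher's exact p = 7.18e-33). Here and below, Fisher's test counts exons or acceptors of the same libraries, so its p does not measure the spread between libraries. Over all tested exons, the 2932 with T were on average -3.42 points lower in S34F, and 78.0% of them were lower. The 4910 with C were 0.50 points higher and the 682 with A 1.79 points higher, while the 70 with G changed by -1.52 points. Camera sets each class of exons against all other exons. With an estimated correlation, it gave T exons a lower relative inclusion (limma camera adjusted p = 0.00402) and no call for G exons (0.834). It gave C exons (0.00402) and A exons (0.00506) a higher relative inclusion. A fall of T exons alone would also raise the other classes in this test, so these calls do not show a separate gain. For C exons the libraries overlapped, with -0.088 points in S34F replicate 1 and 0.29 in WT replicate 3. The mean level of T exons minus that of C exons, relative to the average library, was -1.77, -2.55 and -1.56 points in S34F and 2.25, 1.78 and 1.85 points in WT. The difference was -3.92 points (exact permutation p = 0.1), and it was -4.02, -4.33 and -3.41 points within pairs 1, 2 and 3.

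**Figure D3:**
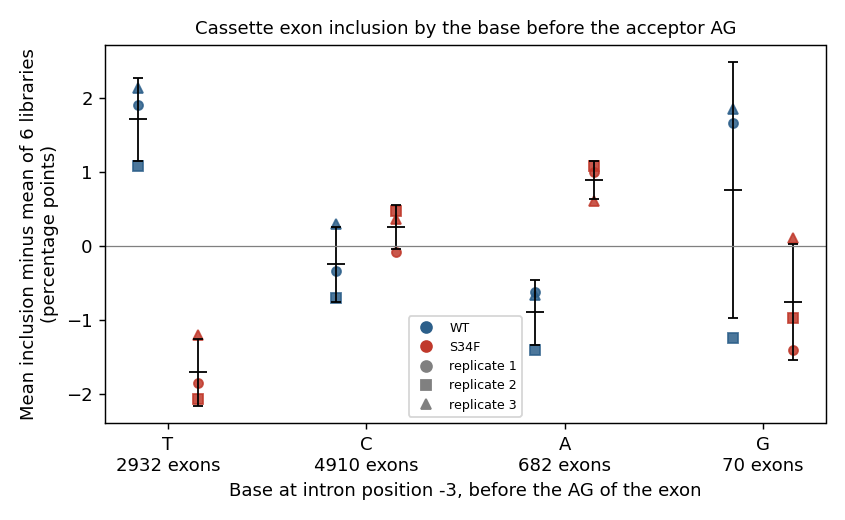
Mean inclusion of cassette exons minus their mean over the 6 libraries (percentage points), by the base at intron position -3, for each library, WT in blue and S34F in red, with bars for the mean ± SD. For T and for A the genotypes lie apart, with T exons between -2.07 and -1.20 in S34F and between 1.08 and 2.14 in WT, while for C and G they overlap.

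The 103 DESeq2 calls were divided in the same way, with 63 lost and 1 gained among T exons and 9 lost and 18 gained among C exons (log2 odds 6.37, Fisher's exact p = 1.66e-11). At alternative 3' splice sites with an unadjusted p under 0.01, acceptors with T were used less 32 times and more 2 times, and those with C less 28 times and more 46 times (log2 odds 4.41, Fisher's exact p = 1.39e-08). Both acceptors of a pair enter and are not independent, and with any single library left out the log2 odds were lower, from 2.41 to 3.33 (4.65 to 7.25 for the cassette exons with an unadjusted p under 0.01). Where the proximal site had T and the distal site C, the proximal share was on average -2.01 points lower in S34F over 793 pairs, and where these were exchanged it was 2.20 points higher over 303 pairs. Pairs with T at both sites (197) or C at both sites (1442) moved by -0.083 and -0.23 points. With the replicate block, the log2 odds at alternative 3' splice sites were 1.19 (Fisher's exact p = 0.326). The test planned on edgeR calls had 0 events to compare, since edgeR gave 232 cassette exons a p under 0.01 but called 0 after adjustment, so the sets used above were chosen after seeing the data.

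**Figure D4:**
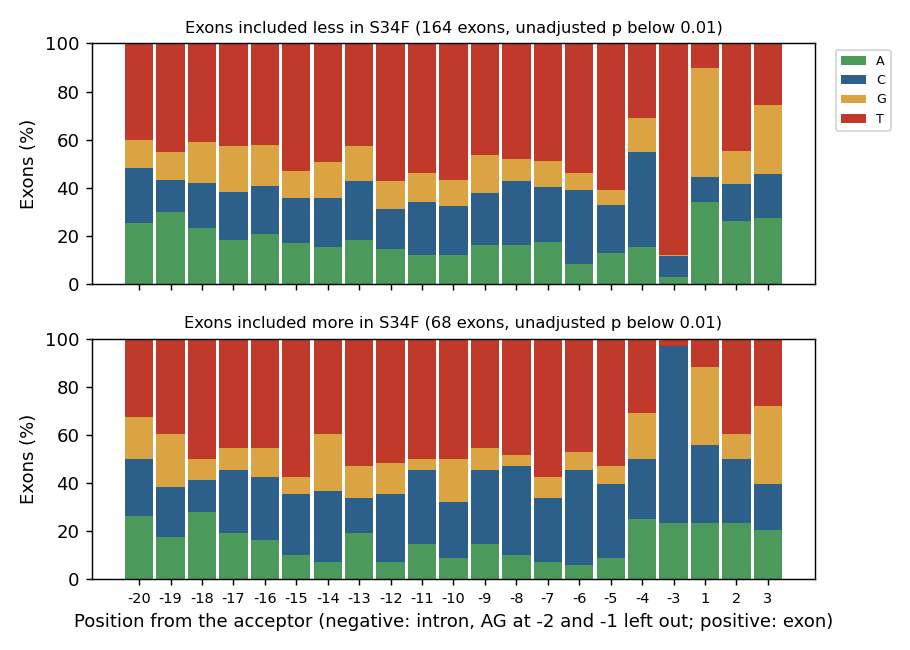
Shares of the 4 bases (%) from intron position -20 to exon position 3 around the acceptor, AG left out, in the 164 lost exons (top) and the 68 gained exons (bottom) with an unadjusted p under 0.01. At position -3, T makes up 87.8% of the lost and 2.94% of the gained exons.

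Genes reported as splicing targets of the S34F mutant were examined as a fixed list, of which 12 genes had 39 tested events. The source of each report was not recorded, so reports that rest on these same libraries were not excluded. For such genes the results below would not be independent support. By edgeR, 5 events passed adjusted over the list alone and 0 over all events, 10 had an unadjusted p under 0.05, and 6 were DESeq2 calls. The 5 were overlapping forms of an exon of H2afy, the gene of the histone variant macroH2A1, at 2.25 ± 0.269% against 4.27 ± 0.368% and 2.26 ± 0.279% against 4.32 ± 0.375%, an exon of Fmr1 (-9.70 points), the Med24 exon and the Picalm acceptor. The H2afy levels average the junctions on both sides of the exon and are not its share of reads at the next acceptor. Both forms use the same downstream junction, so they are not independent events. At its acceptor that junction took 4.26 ± 0.576% of the reads in S34F and 7.96 ± 0.666% in WT. The junction from the neighbouring exon with an end at 56191119 took 94.2 ± 0.705% against 89.6 ± 0.524% there. The events of lowest p in the remaining genes changed by 9.71 points in Gnas, -17.0 in Bcor, 3.02 in Chchd7, -3.34 in Slc35c2, 3.04 in Atr, 18.6 in Mll2, -2.98 in Casp8 and 2.15 in Irak4, none past the threshold. By the calls of the authors' deposited junction table at an adjusted p under 0.10, 7 of 14 list genes had altered splicing where 1.74 would be expected for genes of similar junction reads (permutation adjusted p = 0.0168 over the lists). By that authors' deposited table it was 6 of 14 (0.0840) without junctions that were present in 3 libraries and absent, or nearly so, from the others. By edgeR calls no list passed (2 genes of 7484 with altered splicing). By DESeq2 calls 4 of 14 list genes had altered splicing (permutation adjusted p = 0.0952), and by edgeR at an unadjusted p under 0.01 also 4 of 14 (0.448, and 0.109 by Fisher's exact test without matching). Without matching on reads, Fisher's exact test gave adjusted p = 0.00119 by the authors' deposited table, 0.0110 by that table without those junctions and 0.0325 by DESeq2 calls, so the call from the last 2 sets depended on the matching. By the authors' deposited table the mitosis list and the list of recurrently mutated genes also passed Fisher's exact test (adjusted p = 0.0252 for each), and neither passed the matched test (0.424 for each).

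Few genes were called both in level and in splicing. Of 7396 genes tested for both, DESeq2 called 30 in level and 262 in acceptor or donor use, and 2, Hnrnpa2b1 and Ms4a6c, were in both sets, where 1.06 would be expected (Fisher's exact p = 0.288). By edgeR the overlap was 0 genes, since 0 were called in level, with 1265 at an unadjusted p under 0.05.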

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

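The tests of other splits for cassette exons by edgeR and at an unadjusted p under 0.01, the tests of junctions absent from a genotype, and the tests of a mislabelled library and of sex were chosen only after the results were seen. The test of sex replaced an earlier test, the edgeR count of genes without S34F replicate 1, which was 0 and could not decide. Only 1 library per genotype was male, so a sex difference in the effect of genotype cannot be told from a difference of the replicate 1 pair. The edgeR interaction of genotype and sex called 0 of 13905 genes (lowest adjusted p = 0.0601, 1755 genes at an unadjusted p under 0.05), which therefore says nothing of a sex difference, and no other tool was run for it.

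The 6 libraries make 10 splits into equal groups, too few for a share under 0.05, so the real values are given with the highest value of the other splits. For genes by edgeR the real count was 0, which any split reaches (highest other 0), so this comparison could not decide. At an unadjusted p under 0.05 the count was 1265 against 3249, reached by 2 splits. For genes by DESeq2 it was 96 against 1634, also reached by 2 splits, and for gene lists 13 against 16, reached by 5. The split with 1634 genes joins S34F replicates 1 and 3 with WT replicate 1, which points to a structure of the samples other than genotype. Among the splits that also part all pairs of replicate numbers, the highest counts were 903 genes at an unadjusted p under 0.05, 85 by DESeq2 and 16 lists.

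For splicing, acceptor choices by edgeR were 0 against 4 in another split, donor choices 3 against 4 (reached by 2 splits), cassette exons 0 against 2 and alternative 3' splice sites 0 against 3. Except for donor choices the real count was 0, which any split reaches, so these comparisons could not decide. Cassette exons with an unadjusted p under 0.01 numbered 232 against 63 and cassette exons called by DESeq2 103 against 14. Alternative 3' splice sites with an unadjusted p under 0.01 64 against 28, those called by DESeq2 56 against 16, and the log2 odds of T at position -3 were 7.65 against 3.58. For each of these, only 1 of the 10 splits, the real one, reached the real value, and among splits that part all pairs the highest were 45, 2, 23, 9 and 2.34. Gene lists among genes with altered splicing were 0 against 2 and genes called in both level and splicing 0 against 0. Any split reaches a count of 0, so these could not decide either.

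Several of the junctions with the lowest p in the authors' deposited table had 20 or more reads in every library of a genotype and none or almost none in the other, here called absent at 2 reads or fewer in total. There were 20 such junctions between the genotypes (11 absent from S34F, 9 absent from WT), including junctions of Rplp1, Rpl7a, Rpl39, Rpl14, Arpc1b and Nap1l1. Of these 20, 6 were among the 10 lowest adjusted p-values of that table. Of the 11 junctions absent from S34F, 9.09% had T before the AG (exact 95% interval 0.230% to 41.3%, for counting error only) against 87.8% of the lost cassette exons. This argues against a loss of acceptors with T as their common source. The junctions of Rpl7a, Xpo1 and Eif4g1 shared their acceptor with other forms that took most of its reads, so for these the base says nothing of acceptor choice. A single strain segment is argued against by the spread of the 20 junctions over 13 chromosomes. Discovery of junctions by the aligner library by library is a candidate explanation that stays open, since other splits gave up to 17 such junctions.

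In the dendritic cell and macrophage list 15 of the 23 measured members were lower in S34F and 8 higher (camera adjusted p = 6.27e-10, adjusted p = 0.303 with an estimated correlation), edgeR called 0 over all genes, and 6, among them MHC class II genes, passed adjusted over the list alone, all lower. After thinning all libraries to the smallest, the median log2 fold change of these 6 was -2.37. This cannot decide on library depth as the cause, since random thinning keeps each gene's expected share of its library. The 6 were also chosen by low p in the same data. Fewer cells of the dendritic lineage in the sorted S34F population is a hypothesis that stays open. Cd74, an abundant transcript of such cells, had a log2 fold change of -2.02 (edgeR adjusted p = 0.548), but this rested on WT replicate 1, at 97.4 CPM, while WT replicates 2 and 3 were at 9.89 and 20.2 and S34F replicates at 13.6, 4.27 and 13.5. The sort took lineage-negative cells, and whether it removed all cells of the dendritic lineage was not tested. A change within the progenitors themselves was not excluded either.

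WT replicate 1 stood apart from the other WT libraries in gene counts: after thinning its distance in log2 CPM was 0.441 and 0.440 to S34F replicates 1 and 3, but 0.616 and 0.585 to WT replicates 2 and 3. A mislabelled library is argued against by splicing, where its level of T exons minus C exons was 3.82 points above the highest S34F library. Without WT replicate 1, edgeR called 1169 genes after thinning and 1172 before, so these calls did not need unequal read numbers. This cannot decide on library depth as the cause, since random thinning keeps each gene's expected share of its library. Sex as the whole cause is argued against by distance. WT replicate 1 lay at 0.440 from S34F replicate 3, which differs from it in sex and genotype. This was below its distances to the other WT libraries, which differ from it in sex alone. A batch shared by some libraries stays open, as the labels give none.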

How the results depend on the processing

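Tests by DESeq2 with libraries left out or with the block, without both replicate 1 libraries, without junctions absent (2 reads or fewer) from 3 libraries, on events at an unadjusted p under 0.01, and on DESeq2 or the authors' calls in place of edgeR calls were chosen only after the results were seen. Among values that answer a comparison, 102 stayed the same (on the same side of the threshold, or within 1.5 times for counts), 40 became stronger and 9 weaker. Among values of single genes, events and lists these were 914, 295 and 46, and 3 reversed. No named gene, cassette exon or alternative 3' splice site passed edgeR in the main setting. For these, staying the same means again not passing, so the tally does not measure how well the named results hold. A count that stayed at 0 was also taken as the same. The log2 fold change of U2af1, which passed no test, reversed without WT replicate 1 (-0.0098 by edgeR, -0.012 by DESeq2), in ranges up to 0.13 and 0.14 leaving out each library. The immediate early list reversed without S34F replicate 2, with a camera adjusted p of 9.18e-07 to 0.793 leaving out each library. For these the cause was not tested. The median log2 fold change of all genes was -0.0052, and -0.0043 to -0.0029 with other scalings, which turned no named gene.

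The edgeR count of 0 genes became 2 at a threshold of 0.10, 5 with the replicate block, 599 without both replicate 1 libraries, and 0 to 1172 leaving out each (1 without S34F replicate 3, 1172 without WT replicate 1). DESeq2 gave 96, 445 with the block (81 shared with the 96), 1719 without both replicate 1 libraries (81 shared). It gave 68, 55, 90, 2502, 78 and 43 without S34F replicates 1, 2, 3 and WT replicates 1, 2, 3, of which 45, 44, 55, 84, 50 and 34 were shared. The 13 lists became 0 with an estimated correlation, 12 with the block, 7 without both replicate 1 libraries and 7 to 17 leaving out each (7 without WT replicate 1).

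Acceptor choices were 0 by edgeR, 0 to 0 leaving out each library, 368 by DESeq2, 45 by limma and 355 by DESeq2 without junctions absent from 3 libraries. Donor choices, 3 by edgeR, were 233 by DESeq2, 56 by limma, 226 by DESeq2 and 1 by edgeR without those junctions. By edgeR they were 0 with the block, 0 at 10 points or more and 0 to 5 leaving out each (5 without S34F replicate 2 or WT replicate 2, 0 without WT replicate 1, 1 without WT replicate 3). Cassette exons were 0 by edgeR with each library left out and 2 at a threshold of 0.10. By DESeq2 they were 103, 29 with the block, 46 without both replicate 1 libraries, and 32, 17, 62, 146, 103 and 33 leaving out S34F replicates 1, 2, 3 and WT replicates 1, 2, 3. Alternative 3' splice sites were 0 by edgeR, 56 by DESeq2, 4 by limma and 0 to 2 leaving out each library (2 without S34F replicate 1 or WT replicate 3). The events open to the planned base test, 0 by edgeR, were likewise 0 to 2.

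The log2 odds of T at position -3 stayed positive in every setting run. For cassette exons they were 4.65 to 7.25 leaving out each library (4.98 without S34F replicate 3 or WT replicate 2, 4.65 without WT replicate 1). For alternative 3' splice sites they were 2.41 to 3.33 (2.59, 2.49 and 2.41 without S34F replicates 1, 2 and 3, 2.53 without WT replicate 2) and 1.19 with the block (Fisher's exact p = 0.326). The T minus C level was -4.14 to -3.65 points. Lists among genes with altered splicing went from 0 to 1 with the calls of the authors' deposited table at 0.10, and genes called in level and splicing from 0 to 2 with DESeq2. The block changed no other call of a count or list than those given here and in the report. A minimum of 10 reads per junction removed nothing, since the smallest total was 12, so it tested nothing. For events at the minimum of 20 reads per library, depth limits the inclusion level of each library.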

Other observations

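The test of lists by camera was planned, and the tests of positions around the acceptor, of the downstream acceptor and of exon length were set up before their own results were seen but after the result at position -3. Besides the groups described above, genes of nonsense-mediated decay and its natural targets were higher in S34F in 16 of 22 members (median log2 fold change 0.18, camera adjusted p = 0.000819). So were heat shock genes in 18 of 24 (0.12, 0.00534), genes recurrently mutated in myelodysplastic syndromes and acute myeloid leukaemia in 42 of 58 (0.10, 0.00534) and mature neutrophil genes in 11 of 21 (0.09, 0.0276). Among these DESeq2 called Itgb2l, an integrin gene, at 8.25 ± 0.805 against 3.61 ± 1.26 CPM (log2 fold change 1.19, adjusted p = 0.00554). Ribosomal protein genes were lower in 69 of 82 members (median -0.13, camera adjusted p = 0.00366, but 0.03 in the replicate 1 pair), with shared reads from their many pseudogenes not excluded. Immediate early genes were lower in 22 of 34 (median -0.13, camera adjusted p = 0.0460), with Id2, an inhibitor of differentiation, as the DESeq2 call (log2 fold change -1.13, adjusted p = 0.00496). The median of the immediate early list was -0.05, -0.44 and -0.10 in replicate pairs 1, 2 and 3. Its direction reversed without S34F replicate 2. With an estimated correlation these lists had adjusted p = 0.688, and the immediate early list 0.695.

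The other lists did not pass camera: ribosome biogenesis (adjusted p = 0.0579, with Ncl a DESeq2 call at a log2 fold change of 0.69), DNA replication (0.0675), translation factors (0.140, with Eif5b a DESeq2 call at 0.47), B and T lymphoid (0.140) and stem and early progenitor (0.160). The same held for megakaryocyte (0.190), DNA damage response (0.240), granulocyte-monocyte (0.240), eosinophil, basophil and mast (0.271), and the reported splicing targets (0.271). It also held for cholesterol synthesis (0.545), mitosis (0.609), glycolysis (0.609), stromal and endothelial (0.713, lower by the test with a median of 0.02), unfolded protein response (0.759), inflammation (0.811) and nuclear genes of oxidative phosphorylation (0.831).

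A hypothesis is that the mutant acts mainly on the base before the AG. Over positions -20 to -3 of the intron and 1 to 3 of the exon, the largest absolute log2 odds between lost and gained exons at any position other than -3 was 2.03, for C at exon position 1 (adjusted p = 0.00335), against 7.55 for T at position -3 (adjusted p = 3.20e-35). The largest odds at -3 are consistent with the hypothesis, on exons chosen by their change in the same data, but C at exon position 1 also passed (10.4% of lost and 32.4% of gained exons), so an action limited to that base is not shown.

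A further hypothesis was that skipping also depends on the competing downstream acceptor. T preceded that acceptor in 36.8% of the 68 gained exons and 31.1% of the 164 lost exons, a difference of 5.67 points (Fisher's exact p = 0.443), which leaves the hypothesis undecided.

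A hypothesis was that lost exons whose length shifts the reading frame lower the level of their gene. With 1 lost exon taken per gene, and the gene kept where that exon was fully coding, the median log2 fold change was -0.03 in 71 genes with a frame-shifting exon and 0.09 in 58 with a frame-keeping exon, a difference of -0.12 (permutation p = 0.00871, 100000 permutations across genes, which are not independent replicates). The median of all genes was -0.0052, so the difference came mostly from the genes with a frame-keeping exon, and a lowering of the genes with a frame-shifting exon was not shown. Frame-keeping exons made up 45.0% of these lost exons and 42.8% of the 5415 tested coding cassette exons.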
